A study of Mus musculus with 4 samples.

How the data were processed

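The measurements are RNA-seq read counts from 4 libraries of mouse stomach (C57BL/6), 2 libraries per genotype. Per the labels' protocols, stomachs were opened, pinned flat and frozen, and RNA was taken from several 10 µm cryosections of the pylorus, starting where epithelium first appeared. Poly(A) RNA was made into strand-marked (dUTP) libraries and read from both ends at 75 bp on a NextSeq 500. WT denotes mice with floxed Lats1 and Lats2 and no Cre. Lats1/2 KO denotes mice with the same floxed genes and the tamoxifen-inducible Lgr5-CreER, which recombines them in Lgr5-positive gland-base stem cells, whose progeny inherit the deletion. Both groups were collected 8 weeks after tamoxifen. Sections hold every cell type of the tissue, so a level is an average over recombined and unrecombined epithelium and other cells.

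Per the submitters' processing notes, TopHat2 2.1.1, HTSeq, DESeq2 and the mouse genome build GRCm38 were used; the settings, including whether HTSeq counted by strand, are not given in the sources used here. The table used gives whole-number counts per gene and library, not normalized by the authors. Per the file headers, it also gives the authors' DESeq2 base mean (a signal averaged over normalized counts), their log2 fold change with its standard error, a Wald statistic (a score), a p-value and an adjusted p-value. It holds 2701 genes, and the largest adjusted p-value the authors deposited among them is 0.05. Genes beyond that threshold were not analysed here, so nothing is said of them. From the deposited p-values and adjusted p-values, the number of genes the authors tested was inferred as 13138 (quartiles over genes 13124 and 13151), of which 20.6% are listed. The deposited log2 fold changes are shrunken toward 0: their slope on the log2 ratio of group means is 0.775. They carry no SD or n here.

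The authors' size factors were recovered from the deposited base means and counts as 0.792 and 0.907 for WT 1 and 2 and 1.10 and 1.28 for Lats1/2 KO 1 and 2. Base means rebuilt with them deviated from the deposited ones by at most 0.0119%. Levels are counts divided by these factors (normalized counts), as mean ± SD over 2 libraries. Log2 fold changes with standard errors (SE) are from edgeR 4.0.16 on the same factors, with the low-count filter of filterByExpr for calls and none for the fold changes of list members. Symbols come from GENCODE M21, which matched 2698 of 2701 IDs. Starts in the deposited table lie 1 base below GENCODE's in 2214 of these, so 1 was added to every start that is printed.

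The test fixed for the counts before the data were examined was edgeR's quasi-likelihood test with TMM scaling, genotype as the one factor, and Benjamini-Hochberg adjustment at 0.05. A table that holds only genes already called different fits this test poorly. TMM assumes that most genes do not change, and in this table it shifts every log2 fold change up by 0.361 against the authors' factors (0.407 with DESeq2 1.42.0 size factors computed from the listed genes). The spread is estimated from genes selected for a small p, and adjustment covers 2701 genes in place of 13138. The edgeR counts are therefore printed beside the authors' calls and beside the same test on the authors' factors, and none of them is independent of the authors' selection. In the text, rose and fell refer to genes in the authors' deposited table, at the authors' threshold and on the authors' scale.

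The 33 gene lists and the rule for named genes were also fixed before the data were examined. Because the table is limited by significance, a list was tested by an exact two-sided binomial test of its listed members' directions against the split of all other listed genes, adjusted over the 10 lists with 5 or more listed members. This test treats genes as independent. Beside it, camera (limma 3.58.1) with an estimated correlation was run on log2(normalized count + 1) of the listed genes alone. Its comparison genes were thus also selected for a difference, and with 2 libraries per group the correlation is poorly estimated. With all 31 listed cell cycle genes higher, camera's p before adjustment was still 0.299. A missed threshold in camera therefore decides little. A further test, added after the data were seen, compared the share of a list's annotated members that are listed with the share of all tested genes (hypergeometric), with members lacking a row counted as not passing. Named are Lats1, Lats2, Yap1, Wwtr1, Ccn1, Ccn2, Ankrd1, Amotl2, Myc, Lgr5 and Cd44 where listed, the 10 largest positive and 10 largest negative deposited log2 fold changes at a base mean of at least 100 with groups that do not overlap, and up to 4 members per list with the smallest adjusted p. Unnamed models and pseudogenes were passed over in the ranking. F3, Nt5e, Dock5, Tead2, Vgll3, Vgll4, Mki67, Ccnd1, Muc5ac, Cxcl9, Msln, Scd2 and the 6 ribosomal protein loci are named outside this rule, after their values were seen, and the single values of some genes that the rule names are not reported here.

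On simulated counts for the 2701 genes with 200 changed, edgeR on the given factors recovered 74% of genes raised 2-fold, 68% of genes lowered to 0.5 of their level, and 100% of those changed 4-fold or to 0.25, and called 13 of 2501 unchanged genes. In 1000 random lists of 15 listed genes, the binomial test gave a p under 0.05 in 31. The simulated genes had a common spread setting and were mostly unchanged, whereas every listed gene was selected for a difference. Random lists also ignore the correlation between members, which camera estimated at 0.69 for cell cycle, 0.535 for Myc and 0.916 for interferon-stimulated genes. Neither check therefore gives the error rate of the tests reported here. Python 3.11.15 (scipy 1.17.1), R 4.3.3 and blastn 2.17.0 were used. Counts of the listed genes sum to between 13413629 and 17689207 per library; the totals over all genes were not analysed here. The alternatives tried were other scalings, DESeq2 in place of edgeR, no low-count filter, a replicate block, leaving out each library, and other thresholds. The labels number the libraries 1 and 2 in each group without saying that a number pairs animals, and name no batch. They do not say outright that each library is a separate mouse, so p-values measure the spread between these libraries.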

Results

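RNA from the pyloric stomach was compared between mice able to lose the Hippo kinases Lats1 and Lats2 from Lgr5-positive stem cells and their progeny (Lats1/2 KO, 2 libraries) and floxed mice without Cre (WT, 2 libraries), 8 weeks after tamoxifen. LATS1 and LATS2 phosphorylate and restrain the transcriptional coactivators YAP and TAZ, and the comparison asks which transcripts differ once these kinases are removed. Listed genes held 14315314 and 17689207 counts in WT 1 and WT 2 and 13413629 and 14225132 in Lats1/2 KO 1 and 2. Log-scale levels of the listed genes correlated across genes at r = 0.980 between the WT libraries and 0.979 between the Lats1/2 KO libraries, against 0.840 to 0.922 between groups; the genes were selected for a group difference and are not independent replicates. Replicates differed by far more than sampling noise, with a chi-square of 114 per degree of freedom in WT and 108 in Lats1/2 KO.

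Lats1 (ENSMUSG00000040021, chromosome 10, 7681209 to 7716458, GRCm38) had 2152 and 1974 normalized counts in the WT libraries and 942.5 and 1129 in the Lats1/2 KO libraries. Its mean fell from 2063 ± 125 to 1036 ± 132 (SD, n = 2), a log2 fold change of -0.99 ± 0.17 (SE), and the authors' deposited table gives an adjusted p of 1.43e-05. The direction matches the labels in every library. The count covers the whole gene, so reads outside the floxed exons and from unrecombined cells remain in it. Without Lats1/2 KO replicate 2 the log2 fold change was -1.13 with an edgeR adjusted p of 0.0696. Lats2 was not among the listed genes, so the deletion could not be checked on it.

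All listed genes of the cell cycle list and of the list of Myc and its nucleolar targets rose in the Lats1/2 KO pylorus, and all listed interferon-stimulated and surface mucous genes fell. YAP/TAZ targets went both ways, 5 higher and 3 lower, a split not distinguishable from that of the other listed genes (exact binomial adjusted p = 0.375). The direction test passed for the cell cycle list, the Myc list and interferon-stimulated genes. It missed the threshold for surface mucous genes (exact binomial adjusted p = 0.0557). With an estimated correlation, camera gave each of these 4 lists an adjusted p = 0.557. Run on the listed genes alone with 2 libraries per group, camera had little power, so this value settles nothing about the lists. Ajuba and Ccn2 rose 6.31-fold and 5.07-fold, and Myc rose 2.55-fold. Gkn2, which encodes a secreted protein of gastric surface mucous cells, fell 2.16-fold. Among 2701 genes in the authors' deposited table, 1158 rose and 1543 fell (42.9% higher), and 559 and 366 of them did so with an absolute log2 fold change of at least 1.

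**Figure D1:**
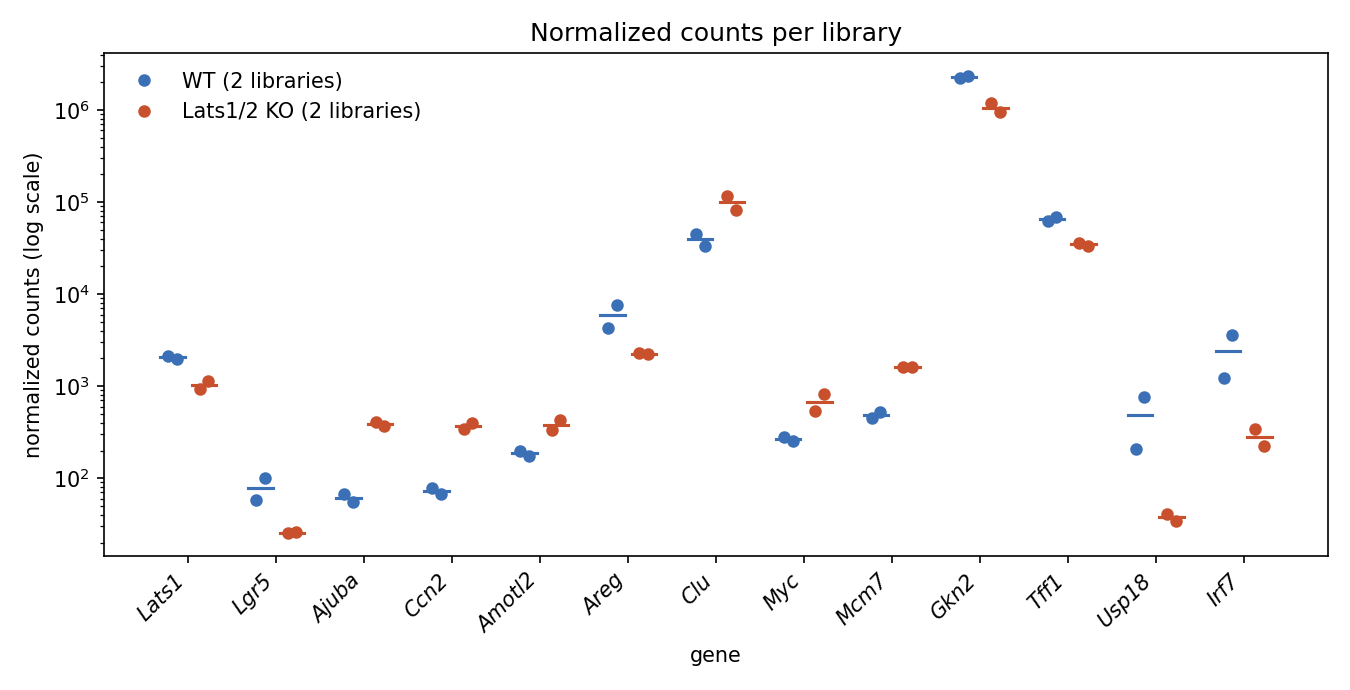
Normalized counts (logarithmic vertical axis) of 13 genes in each WT library (blue) and each Lats1/2 KO library (orange), with horizontal bars at group means. Ajuba lies at 68.1 and 55.2 in the WT libraries and at 403.8 and 373.6 in the Lats1/2 KO libraries, and Usp18 at 205.7 and 768.7 against 40.7 and 34.4.

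Of 24 YAP/TAZ targets, 8 were listed, 5 higher and 3 lower. Ajuba (chromosome 14, 54567469 to 54577661), a LIM protein that binds LATS kinases, rose from 61.7 ± 9.19 to 388.7 ± 21.4 normalized counts (SD, n = 2), a log2 fold change of 2.66 ± 0.28 (SE). Ccn2 (chromosome 10, 24595442 to 24598683), a secreted matrix-associated protein and standard YAP reporter, rose from 72.8 ± 7.75 to 369.2 ± 39.4, or 2.34 ± 0.27. Ptpn14 rose by 1.65 ± 0.29, Amotl2 by 1.02 ± 0.25 and F3, which encodes tissue factor, by 1.06 ± 0.33 on the log2 scale. Areg, an EGFR ligand, moved the other way, from 5923 ± 2336 to 2252 ± 20.2, as did Nt5e and Dock5, whose adjusted p on the TMM scale were 0.0966 and 0.133; F3, Nt5e and Dock5 are named outside the rule, after their values were seen. The split was not distinguishable from that of the other listed genes (exact binomial p = 0.300, adjusted p = 0.375). Yap1, Wwtr1, Ccn1 and Ankrd1 were not among the listed genes and have no values here.

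Among 24 Hippo pathway components, 5 rose and 2 fell (exact binomial p = 0.146, adjusted p = 0.286). Tead4 and Tead2, DNA-binding partners of YAP, rose by 1.66 ± 0.37 and 1.07 ± 0.29 on the log2 scale, and Wwc2 rose from 807.7 ± 32.2 to 1576 ± 194 normalized counts (SD, n = 2). Vgll3 and Vgll4, which encode TEAD cofactors, also rose, Vgll3 by a log2 fold change of 2.22 that was 1.36 without Lats1/2 KO replicate 2. The rule does not cover Tead2, Vgll3 and Vgll4, which were chosen after their values were seen. The 2 falls were in Lats1 and the kinase gene Taok3. Lats1 was deleted by design, so its direction, which the test counts, is no response of the pathway. Taok3 had a log2 fold change of -0.64 ± 0.16 (SE) and an edgeR adjusted p on the TMM scale of 0.120.

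Of 33 cell cycle genes, 31 were listed and all 31 rose, by a median log2 fold change of 1.36 (0.57 to 2.07). The median was 1.07 without WT replicate 1 and 1.735 without WT replicate 2, its lowest and highest values without a single library. The replicative helicase genes led by significance: Mcm7 (chromosome 5, 138164583 to 138172422) went from 484.1 ± 54.7 to 1615 ± 7.53 normalized counts (SD, n = 2), Mcm2 rose 3.50-fold, Mcm3 3.72-fold and Mcm6 2.43-fold. Mki67, a marker of cycling cells, rose 2.37-fold and Ccnd1 1.81-fold, both chosen after their values were seen. The list's direction differed from that of other listed genes (exact binomial p = 2.44e-12, adjusted p = 2.44e-11), while camera gave an adjusted p = 0.557 with an estimated correlation.

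Myc (chromosome 15, 61985341 to 61990374) rose from 266.9 ± 18.7 to 680.7 ± 197 normalized counts (SD, n = 2), a log2 fold change of 1.35 ± 0.27 (SE). Within the list of Myc and its nucleolar targets, 30 of 34 members were listed and all 30 rose, by a median of 1.26 on the log2 scale. Without a single library that median ranged from 0.997 (Lats1/2 KO replicate 2 left out) to 1.44 (Lats1/2 KO replicate 1 left out). Fbl, the methyltransferase of box C/D snoRNPs, rose 2.52-fold, the nucleolar protein gene Mybbp1a 3.90-fold, Cad, which starts pyrimidine synthesis, 3.70-fold and the cyclin-dependent kinase gene Cdk4 2.22-fold. The exact binomial p was 5.88e-12 (adjusted p = 2.94e-11), and camera gave an adjusted p = 0.557 with an estimated correlation.

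Interferon-stimulated genes fell: 18 of 20 were listed, none higher, with a median log2 fold change of -3.26. Usp18 (chromosome 6, 121245906 to 121270917), a deconjugase of ISG15, went from 487.2 ± 398 to 37.6 ± 4.49 normalized counts (SD, n = 2), Irf7 from 2392 ± 1650 to 281.7 ± 84.4, Gbp2 from 3950 ± 2368 to 564.3 ± 61.8 and Oas1a from 1861 ± 751 to 431.5 ± 102. The WT libraries stood apart, with WT 2 at 768.7 and WT 1 at 205.7 counts of Usp18, and the list's median was -2.07 without WT replicate 2 and -3.94 without WT replicate 1. Without WT replicate 2 the log2 fold changes of Usp18, Irf7 and Gbp2 were -2.45, -2.12 and -2.01 in place of -3.70, -3.09 and -2.81, and without WT replicate 1 Usp18 was at -4.35. The exact binomial p was 4.50e-05 (adjusted p = 1.50e-04), and camera gave an adjusted p = 0.557 with an estimated correlation. Antigen presentation had 4 of 15 members listed, all lower, with wide spread in WT: B2m went from 27385 ± 25266 to 4516 ± 1004 normalized counts (SD, n = 2) and Tap1 from 2410 ± 2155 to 335.7 ± 140. Without WT replicate 2, the log2 fold changes of B2m, Tap1, Tap2 and H2-D1 were -1.07, -1.40, -0.78 and -0.67 in place of -2.60, -2.85, -1.56 and -1.51; without WT replicate 1, B2m and Tap1 were at -3.32 and -3.55. H2-D1 belongs to a family of similar class I genes whose reads the counting could divide, and its adjusted p on the TMM scale was 0.0553.

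Surface mucous genes fell as well, with 7 of 11 listed and none higher, by a median log2 fold change of -0.91 (-1.11 to -0.68). Gkn2 (chromosome 6, 87373357 to 87379497) went from 2291739 ± 76102 to 1062604 ± 174452 normalized counts (SD, n = 2) and Gkn1 from 1766005 ± 10926 to 841418 ± 202310. Both gastrokines together took 22.1% and 21.1% of listed counts in the WT libraries and 17.9% and 14.7% in the Lats1/2 KO libraries. The trefoil peptide gene Tff1 fell 1.88-fold, the calpain gene Capn9 2.15-fold and the mucin gene Muc5ac 1.88-fold, the last chosen after its values were seen and with an adjusted p of 0.196 on the TMM scale. The direction test missed the threshold after adjustment (exact binomial p = 0.0223, adjusted p = 0.0557; camera adjusted p = 0.557 with an estimated correlation). The share of members listed was higher than that of all tested genes (hypergeometric adjusted p = 0.0191 over 33 lists), a comparison chosen after the data were seen. It took no account of expression level. High counts such as those of Gkn1 and Gkn2 make a given change easier to call, so the share may reflect abundance.

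**Figure D2:**
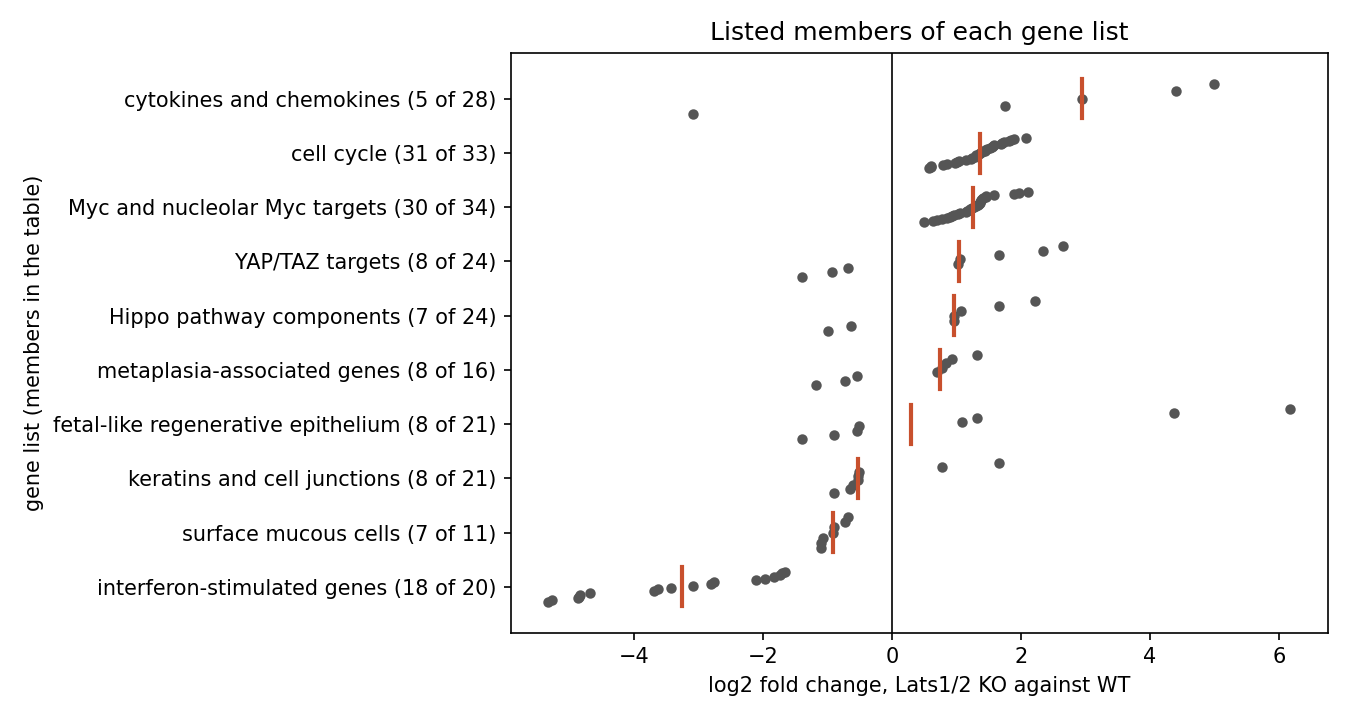
Log2 fold change of Lats1/2 KO against WT (horizontal axis) for each listed member (grey points) of the 10 lists with at least 5 listed members, with the list's median as an orange bar; labels give listed and annotated members. All 31 cell cycle and all 30 Myc list members lie right of 0, and all 18 interferon-stimulated and all 7 surface mucous members lie left of it.

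Fetal-like regenerative genes split evenly, with 8 of 21 listed, 4 higher and 4 lower (exact binomial p = 0.731, adjusted p = 0.731). Clu, which encodes clusterin, rose from 39531 ± 8403 to 98879 ± 23695 normalized counts (SD, n = 2) and Anxa1 rose 2.11-fold, while the surface keratin Krt20 fell 1.87-fold. Msln, named outside the rule after its values were seen, went from 36.5 ± 37.6 to 750.1 ± 225, a log2 fold change of 4.38 that was 6.22 without WT replicate 1 and 3.57 without WT replicate 2. Metaplasia-associated genes had 8 of 16 members listed, 5 higher and 3 lower (exact binomial p = 0.300, adjusted p = 0.375): Gpx2 rose 1.62-fold, and Mucl3 and Mal2 fell 1.65-fold and 1.45-fold, both short of the threshold on the TMM scale (adjusted p = 0.110 and 0.210).

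Of the Wnt target and stem cell list, 3 of 23 members were listed. Lgr5 (chromosome 10, 115450311 to 115587780), the stem cell gene after which the CreER allele is named, fell from 79.2 ± 29.9 to 25.6 ± 0.311 normalized counts (SD, n = 2), with an adjusted p of 0.0411 in the authors' deposited table and 0.0629 on the TMM scale. Only the Lats1/2 KO mice carry that allele, so its effect on Lgr5 counts cannot be told apart from that of the deletion. Lrig1 and Znrf3, both feedback regulators of growth signalling, rose 1.86-fold and 1.96-fold. Cd44 was not among the listed genes and has no values here. In the Notch pathway, Notch1 and Notch2 rose 1.98-fold and 1.72-fold and the ligand gene Jag1 fell 2.01-fold, from 3 of 16 members.

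Other gastric lineages had few listed members, too few for a test. Of parietal cell genes, 3 of 14 were listed and fell: the potassium channel gene Kcnj15 by 1.71, the carbonic anhydrase gene Car2 by 0.58 and the exchanger gene Slc9a4 by 0.50 on the log2 scale, the last 2 short of the threshold on the TMM scale (adjusted p = 0.188 and 0.327). Of enteroendocrine genes, 2 of 20 were listed and rose, with wide spread: the hormone gene Ghrl went from 37.9 ± 5.27 to 767.2 ± 737 normalized counts (SD, n = 2) and Sst from 30.0 ± 12.1 to 204.2 ± 188. Without Lats1/2 KO replicate 2 their log2 fold changes were 2.70 and 1.24 in place of 4.34 and 2.76, and without Lats1/2 KO replicate 1 they were 5.08 and 3.48. Dmbt1 rose 1.91-fold as the 1 listed gene of 8 neck and antral gland mucous markers. Rab3d, 1 of 9 chief cell genes, fell 1.33-fold, with a TMM adjusted p of 0.705. Avil, 1 of 12 tuft cell genes, fell 1.79-fold. Of 24 intestinal genes, Fabp2 and Vil1 fell 4.77-fold and 2.37-fold and Lyz1 went from 53.3 ± 30.7 to 197.5 ± 14.0, a log2 fold change of 1.88 that became smaller without WT replicate 1 and 2.64 without WT replicate 2. Of 20 squamous genes, Dmkn rose by 3.35 on the log2 scale (2.66 without Lats1/2 KO replicate 1), Krt4 rose 3.16-fold, and Sprr2a1 fell 3.15-fold.

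Keratin and junction genes had 8 of 21 listed, 2 higher and 6 lower (exact binomial p = 0.480, adjusted p = 0.533). Cdh1, which encodes E-cadherin, fell 1.43-fold and the desmosomal gene Dsp 1.58-fold, with TMM adjusted p of 0.291 and 0.0735, while Pkp1 rose 3.17-fold. The epithelial-mesenchymal list had 4 of 20 members listed, among them Cdh1, Itgav and Lamb3, all lower with log2 fold changes from -0.54 to -0.50. These 3 missed the threshold on the TMM scale (adjusted p from 0.291 to 0.313).

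Markers of other cell types were mostly without rows. Cytokine and chemokine genes had 5 of 28 members listed, 4 higher and 1 lower (exact binomial p = 0.172, adjusted p = 0.286). Cxcl5 rose from 4.57 ± 2.90 to 152.7 ± 40.2 normalized counts (SD, n = 2), and the other neutrophil attractants Cxcl1 and Cxcl2 were at 128.8 ± 112 and 100.5 ± 101 in Lats1/2 KO against 16.6 ± 10.9 and 4.49 ± 4.57 in WT. Ccl20 rose by 1.75 on the log2 scale (0.87 without Lats1/2 KO replicate 1), and the interferon-induced Cxcl9, chosen after its values were seen, was at 28.8 ± 13.1 against 245.1 ± 291 in WT (TMM adjusted p of 0.0772). These values moved with single libraries: without 1 library in turn the log2 fold changes ranged from 4.50 to 5.85 for Cxcl5 (highest without WT replicate 2), from 1.57 to 3.85 for Cxcl1 and from 2.61 to 6.19 for Cxcl2 (both lowest without Lats1/2 KO replicate 2 and highest without WT replicate 2), and from -3.97 to -0.45 for Cxcl9 (without WT replicate 1 and without WT replicate 2). Of 24 fibroblast and matrix genes, Thbs1 rose 3.14-fold, and Col3a1, Col1a2 and Mmp2 fell 1.69-fold, 1.72-fold and 2.05-fold, short of the threshold on the TMM scale (adjusted p from 0.0748 to 0.0844). The endothelial receptor gene Kdr fell 1.73-fold (TMM adjusted p of 0.183) as 1 of 13 markers, and the myeloid gene Cd14 rose 2.42-fold as 1 of 20. Among adipocyte-associated genes, Cidec and Pparg fell 2.99-fold and 1.94-fold (2 of 11). Pancreatic Cela1 rose 1.97-fold and Cela2a (2 of 18 with Cela1) was at 6.31 and 215.1 normalized counts in WT 1 and WT 2 and at 3.62 and 0.782 in Lats1/2 KO 1 and 2, so that its listed fall rests on WT 2, and edgeR's low-count filter removed it. Ier3 fell 2.05-fold as 1 of 21 immediate-early and heat-shock genes. No member was listed of the smooth muscle, T and NK cell, B and plasma cell, erythroid, enteric neuron and glia, or sex-linked lists. Adjustment over each list alone set members lacking a row to a p of 1. Every listed member of every list passed it except the 3 of the Wnt and stem cell list and Kdr. All had already passed the authors' threshold over all genes tested, so passing was largely fixed by that selection.

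By the authors' shrunken log2 fold changes, the 10 largest rises at a base mean of at least 100 included Lrg1, Nptx2, Ghrl, Dmkn, Map2, Lemd1, Sftpd, Nfe2l3 and Serpina3n. Lrg1, a secreted glycoprotein of acute inflammation, rose from 58.4 ± 28.0 to 782.6 ± 157 normalized counts (SD, n = 2). Sftpd, a collectin of mucosal surfaces, rose from 239.9 ± 18.0 to 1820 ± 904, and the acute-phase gene Serpina3n rose 7.37-fold. Map2, a microtubule-associated protein gene, and the transcription factor gene Nfe2l3 rose 8.30-fold and 9.30-fold. The 10 largest falls by the same values were in Rtp4, Usp18, Acer1, Irf7, Gbp2, Irgm2, Dmp1, Xaf1, Ifit3 and Oas2, most of them interferon-induced. Ranked instead on edgeR's unshrunken log2 fold changes, an order tried after the data were seen, 8 of these 10 rises and 4 of these 10 falls remain among the 10 largest. Acer1, an alkaline ceramidase gene, fell from 1107 ± 320 to 157.1 ± 60.8, and Rtp4 from 984.2 ± 728 to 52.0 ± 16.1. Dmp1 went from 551.5 ± 532 to 47.6 ± 4.35, so that its WT spread nearly equalled the WT mean. Without WT replicate 2 the log2 fold changes were -3.17 in place of -4.24 for Rtp4, -1.88 in place of -3.53 for Dmp1, -2.03 in place of -2.97 for Irgm2, -2.06 in place of -2.85 for Xaf1, -2.32 in place of -3.64 for Ifit3 and -3.65 in place of -4.88 for Oas2; Rtp4, Dmp1, Ifit3 and Oas2 were more negative, at -4.85, -4.28, -4.32 and -5.53, without WT replicate 1, and Ifit3 at -4.63 and -3.04 without Lats1/2 KO replicates 1 and 2. Among the rises, Lrg1 and Nptx2 were at 3.32 and 2.90 without WT replicate 2 and at 4.34 and 4.18 without WT replicate 1, in place of 3.75 and 3.41. Sftpd was at 2.30 without Lats1/2 KO replicate 1 and at 3.36 without Lats1/2 KO replicate 2, in place of 2.92.

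Pseudogenes were passed over in that ranking, and those of ribosomal proteins, singled out after their values were seen, had the smallest p in the authors' deposited table. Rps3a3 (chromosome 13, 108670603 to 108671397) stood at 2442 ± 266 normalized counts in WT and 53.7 ± 8.07 in Lats1/2 KO (SD, n = 2), and Gm8730 (chromosome 8, 102864779 to 102865853) at 425.8 ± 56.3 and 7001 ± 303. Gm8730 and Gm9625 match the coding transcript of Rplp0 at 98.7% and 97.4% of bases, and Rps3a3 and Rps3a2 match Rps3a1 at 98.9% and 99.5%. All 6 are uncertain, since the counting could divide reads between copies. Rplp0 was at 28505 ± 904 in WT and 19481 ± 922 in Lats1/2 KO, and Rps3a1 at 15387 ± 1085 and 20887 ± 400. Genes of the Oas, Ifit, Lyz and Gst families also have close paralogs and carry the same doubt.

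**Figure D3:**
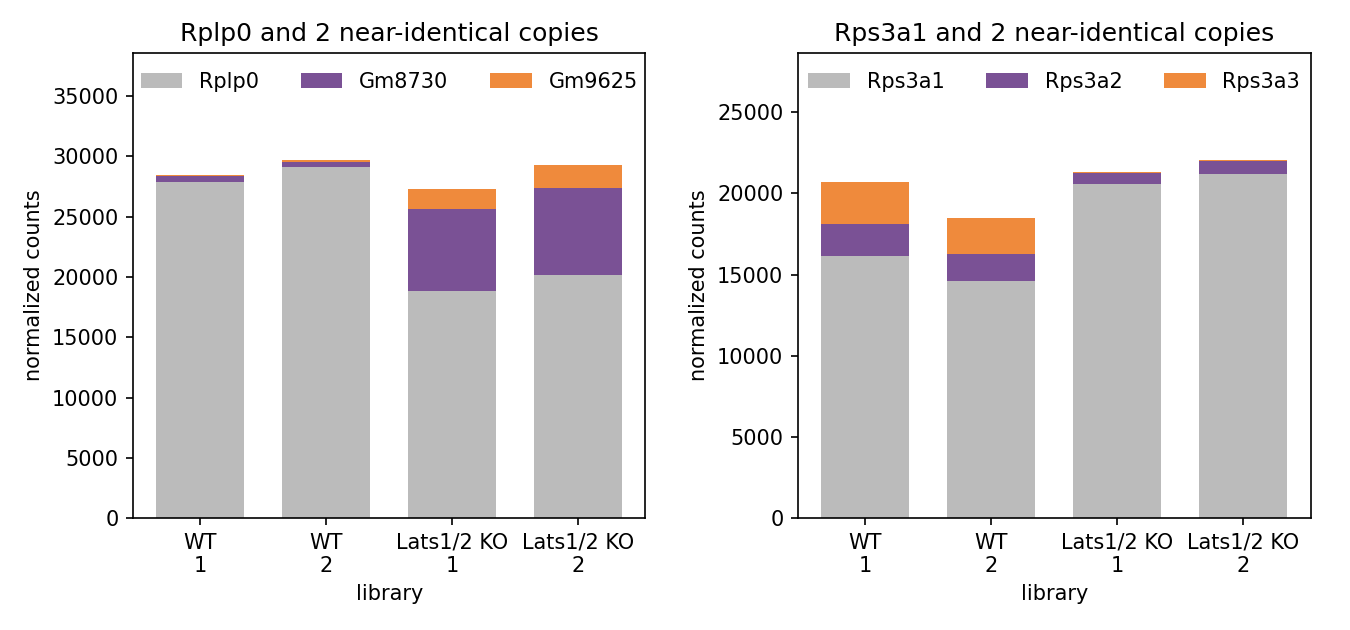
Normalized counts per library (vertical axis, from 0) of Rplp0 with its copies Gm8730 and Gm9625 (left) and of Rps3a1 with its copies Rps3a2 and Rps3a3 (right), stacked. The sum for Rplp0 and its copies averages 29044 in WT and 28282 in Lats1/2 KO, while the part counted on the copies goes from 538.2 to 8801.

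On the TMM scale fixed beforehand, edgeR called 1652 of the 2701 genes, 1157 higher and 495 lower. On the authors' scale it called 2698, 1157 higher and 1541 lower. The number of called falls, and so the balance among called genes, thus depended on the scaling. In both fits 0 genes had a sign other than the deposited one, which their selection for a difference made likely. Adjusted over the 13138 genes tested in place of the listed ones, the authors' scale left 4 genes, Rps3a3, Gm8730, Gm9625 and Scd2, and the TMM scale 904; without Lats1/2 KO replicate 2 the authors' scale left 5 and TMM 940.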

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

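The adjustment over all genes tested, the crossed pairing, the authors' scale, fold changes of single genes on it, and the list signs per library or under TMM were chosen after the data were seen; for Lats1 the values without each library were planned, but not their scale. edgeR on the TMM scale called 1652 genes. It called 860 at an adjusted p under 0.01, 904 when adjusted over the genes the authors tested, and 940 to 1614 without 1 library. On the authors' scale the count of 2698 became 4 at 0.01 or over the genes tested, 1082 at an absolute log2 fold change of at least 1, and 5 to 2452 without 1 library, lowest without Lats1/2 KO replicate 2 and at 1531 without Lats1/2 KO replicate 1. DESeq2 on that scale called 797 without Lats1/2 KO replicate 2, 1427 without Lats1/2 KO replicate 1, 1244 without WT replicate 2 and 1826 without WT replicate 1. A fit without 1 library assumes that the lone library varies like the other group. The 2701 calls of the authors' deposited table became 1637 at 0.01, 925 at an absolute log2 fold change of at least 1 and 683 with Bonferroni adjustment over the listed genes. Stricter thresholds and wider adjustment lower a count by construction; the cause of the fall without a single library was not tested beyond the smaller number of libraries. With no low-count filter, DESeq2, DESeq2 size factors, a threshold of 0.1 or a base mean of at least 100, edgeR's count on the TMM scale stayed within 1.5 times.

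Deviations of same-numbered libraries from their group means correlated at -0.162 across genes. With 2 libraries per group the crossed value is then 0.162 by construction, so neither shows whether the number pairs libraries. The replicate block gave 1536 genes on the TMM scale and 2534 on the authors' scale, and for Lats1 a log2 fold change of -0.997. The crossed pairing gave 1699 and 2662. The fall of Lats1 ranged from -1.13 to -0.87 without 1 library, past the threshold in all but the fit without Lats1/2 KO replicate 2.

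With an estimated correlation 0 lists passed in camera, in place of 3. Camera had little power on the listed genes with 2 libraries per group, so this count does not decide between the tests. The direction test gave 3 lists in the other settings, which says nothing about stability: the genes were selected for a difference in these same libraries, so their signs could hardly move. Of 96 other genes (those named by the rule and the 6 ribosomal protein loci), 18 missed the threshold on the TMM scale, 0 in the replicate block, 92 in edgeR without Lats1/2 KO replicate 2, and 31 in DESeq2 without it; 0 changed sign in any of these. The pseudocount and quantile normalization were not run because counts were used, nor was the log2 fold change as a list statistic, because the list test uses directions alone. With 2 libraries per group, and no values for genes beyond the authors' threshold, unchanged genes cannot serve as a reference.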

Other observations

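The gene families and all tests in this part were chosen after values were seen, so no test of a family's direction is given. Enzymes of nucleotide and one-carbon synthesis rose together: 19 of 24 members were listed and all 19 rose, by a median log2 fold change of 1.25. Ctps, the CTP synthase gene, rose 4.44-fold, Mthfd1 3.42-fold, the first purine-pathway enzyme gene Ppat 3.32-fold and Shmt1 3.07-fold. Nucleoporin genes had 13 of 22 members listed, all higher, led by Nup210 at 3.25-fold, and 9 of 18 RNA polymerase subunit genes were listed and rose, among them Polr1a at 2.93-fold.

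Lipid genes went both ways. Scd2 (chromosome 19, 44293676 to 44306864), a stearoyl-CoA desaturase gene, rose from 4231 ± 343 to 18646 ± 184 normalized counts (SD, n = 2), Fads2 rose 5.98-fold and Elovl5 2.41-fold, while Me1 fell 2.52-fold and Acacb 3.15-fold; 9 of 13 listed genes of fatty acid synthesis and desaturation rose. All 12 listed genes of fatty acid oxidation and triglyceride synthesis fell, with Cpt1a 2.04-fold and Slc25a20 2.66-fold lower. Of 22 glutathione transferase genes, 9 were listed and fell, including Gsta1 from 110979 ± 24290 to 46058 ± 7802; close paralogs make the single values uncertain. On the TMM scale, shifted by 0.361, 6 of the 9 glutathione transferase genes missed the threshold in edgeR. So did 3 of the 12 genes of oxidation and triglyceride synthesis and 1 of the 13 of synthesis and desaturation. In these families 0 genes changed sign, which says little, since genes listed for a difference could hardly do so under a uniform shift. All 7 listed mitochondrially encoded genes fell.

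The ribosomal protein copies moved against their coding genes. Normalized counts on Gm8730 and Gm9625 went from 538.2 ± 42.0 to 8801 ± 447 (SD, n = 2) while Rplp0 fell by 9024, and counts on Rps3a3 and Rps3a2 went from 4227 ± 486 to 783.8 ± 108 while Rps3a1 rose by 5501. With the authors' factors, the summed counts of each coding gene and its copies changed by at most 0.144 on the log2 scale. Reads of the same transcript divided between near-identical copies would give this. These top-ranked changes may be an assignment of reads and not a change in transcription. The TMM scale moves every log2 fold change up by 0.361, so the small change of the sums holds with the authors' factors alone. On the TMM scale the fall of Rplp0 was not called (edgeR adjusted p = 0.2075). The tables argue against a segment carried with the Lgr5-CreER allele on chromosome 10 as the source, since 0 of the 6 loci lie on that chromosome, and 13.6% of coding genes within 20 Mb of Lgr5 are listed against 11.9% elsewhere (Fisher's exact p = 0.331). Sequence variants between the mice elsewhere in the genome stay open, as untested, and so does the genotype itself.

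The fall of interferon-stimulated genes could rest on WT 2 alone, where Usp18 stood at 768.7 normalized counts against 205.7 in WT 1. Without WT replicate 2 the median log2 fold change of the 18 listed members was still -2.07 (-3.94 without WT replicate 1). WT 1 thus also stood above Lats1/2 KO for these members, though the size of the fall depends on WT 2. The value is no independent check, since the members were listed for a difference in these same libraries and only WT 1 remains in it. Immune cells in the WT sections cannot be told apart from an epithelial response: of 53 markers of T and NK, B and myeloid cells, 1 was listed and 0 were lower, and genes without rows have no values here. A difference in exposure of the mice and an effect of the genotype both stay open.

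Surface mucous genes may be lower because of the scaling of the libraries or because the sections held a lower share of surface mucous cells, and the tables settle neither. On the TMM scale their median log2 fold change was -0.55 in place of -0.91, but that scale moves every gene by about the same amount (0.361, with an SD over genes of 0.00742), so the value follows from the shift and says nothing about which scale is right. The 7 falls had an SD of 0.175 on the log2 scale against a median SE of 0.187, a ratio of 0.935. A lower share of these cells would lower all 11 members alike, but 4 have no row, and the authors' threshold narrows the spread among the 7 that do. The ratio was settled on after another measure of the same spread had been seen. The scaling, fewer such cells through a different depth of sectioning and fewer through the genotype all stay open.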
